A study of Mus musculus with 12 samples.

How the data were processed

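Total RNA from mouse fetal livers at E12.5 and from immortalized MEFs, WT or G2A, was isolated with Trizol and sequenced by BGI, per the labels. After trimming to a length of 50 bp, reads were aligned to mm9 with TopHat 2.1.1, per the labels' protocols; the submitters' processing notes list TopHat2 2.1.1, Cufflinks 2.2.1 and both mm9 and mm10. The liver values are FPKM and the MEF values a normalized signal per gene, both made by the authors before deposit. The liver header names no unit, and FPKM was read from the named tool and from the values, which are not whole. Tested on the values, each MEF column held whole reads divided by 1 size factor per library (0.958 to 1.06; all values whole within 0.01 after rescaling). The annotation, the counting tool, the source of the size factors and whether counting used strand are not given in the sources used here. Near-identical genes, such as the adult alpha globins or Hspa1a and Hspa1b, and overlapping genes are therefore uncertain.

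The liver values covered 23235 entries and 6 libraries, the MEF values 24421 entries and 5 libraries. Columns were matched to samples by the tissue, genotype and number in their names. The labels give 3 samples in each of 4 groups. The MEF columns carried WT 1 to 3 and G2A 1 and 2, so 11 libraries were used, without G2A MEF 3.

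Within each tissue log2(value + 1) was fitted on genotype with limma 3.58.1 in R 4.3.3 (moderated test with a variance trend). The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Liver genes had FPKM of at least 1 in at least 3 libraries (12938 genes). The design foresaw the same FPKM filter for MEFs; since that table holds normalized reads, the filter there was at least 10 in at least 2 libraries (13241 genes), set after seeing the data. The G2A effects in liver and MEFs were compared over 10818 genes by the difference of both log2 fold changes over its combined standard error, with Satterthwaite degrees of freedom and Benjamini-Hochberg adjustment. No library is shared between the tissues. The FPKM and the normalized reads were never compared directly.

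Sets of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a tissue, and for the difference between tissues with its version for preranked values. Camera with an estimated correlation and fry were alternatives; the former also takes its degrees of freedom from the number of libraries, where the preset takes them from the number of genes. The tests, the named-gene rule and 36 lists were fixed before the data were examined: proteasome subunits, proteasome assembly and activators, immunoproteasome and MHC class I, ER-associated degradation, unfolded protein response chaperones, integrated stress response, heat shock, NRF2, p53 targets, type I interferon, autophagy and lysosome, cholesterol synthesis, hypoxia and glycolysis, cell cycle, receptor tyrosine kinases, integrins and adhesion molecules, extracellular matrix, inflammatory secretory factors, developmental signalling targets, Hox genes, embryo sex, and markers of erythroid cells, primitive globins, heme synthesis, hepatoblasts, haematopoietic progenitors, macrophages, megakaryocytes, endothelium, liver mesenchyme and mesothelium, smooth muscle, skeletal muscle, adipocytes, cartilage and bone, epithelium and neural cells. In MEFs 35 were tested, since a list needed 3 measured members and primitive globins had fewer.

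Some lists share members: mesenchyme with extracellular matrix, receptor kinases and smooth muscle; receptor kinases also with endothelium, progenitors and macrophages; integrins with endothelium, epithelium and megakaryocytes; erythroid with heme synthesis; hepatoblasts with epithelium and adipocytes. Named genes were Psmc1, Nmt1 and Nmt2; per direction the 10 with the largest change among genes past the threshold whose groups did not overlap, or, with fewer than 5, the 5 with the smallest p; from each list up to 4 members past the threshold or up to 2 with the smallest p; and the 5 largest differences between tissues in each direction among genes past that test. Embryo sex genes served only to read the sex of a library. Not every gene that this rule selects is reported here.

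Simulated data had 100 changed genes per fold size but no outlying library or correlation between genes, so recovery in real data can be lower. The changed genes were drawn only from genes with higher mean values, so recovery among genes at low values was not tested. At a log2 change of 1 limma recovered 90% of changed genes in liver and 19% in MEFs, and 97% and 65% at 3. False calls were 7 and 1. On simulated MEF reads of 13261 genes edgeR recovered 8% and 76%, with 4 false calls. Gene positions, transcript lengths and GC content came from an annotation of NCBIM37, with lengths for 95.2% of liver and 89.0% of MEF genes tested. The alternatives were a pseudocount of 0.1 in place of 1, no filter or a stricter one (5 FPKM or 50 normalized reads), median-ratio scaling, quantile normalization, robust moderation, no variance trend, the label number as a replicate block, leaving out each library, embryo sex as a covariate, and list members shared between lists left out. Chosen after seeing the data were leaving out small RNA genes, library weights, the sex of the MEF line as a covariate, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered MEF reads, edgeR without WT MEF 3, the ER-associated degradation list without Derl3, and removal of a smooth trend on transcript length and GC content (loess span 0.5). No scaling moved the median log2 fold change of all genes by as much as 0.1.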

Results

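RNA sequencing compared wild-type (WT) and G2A mouse fetal livers at E12.5 and immortalized mouse embryonic fibroblasts (MEFs), labelled as 12 samples in 4 groups of 3. As background, G2A is a knock-in allele of Rpt2, a proteasome ATPase encoded by Psmc1, that replaces the glycine to which the N-myristoyl lipid anchor is attached. The liver values held 3 libraries per genotype in FPKM, with column totals of 792987 to 840762, and their read depth is unknown. The MEF values held 3 WT and 2 G2A libraries of 36415586 to 37695116 gene reads each. For the third G2A MEF sample no matching column was found, so it was not analysed here. The labels described the livers as 3 pairs of WT and G2A littermates and gave nothing on whether the MEF libraries came from separate cultures or lines. The p-values therefore measured only the spread between these samples.

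The first comparison asked which mRNAs differed between G2A and WT fetal liver. Proteasome subunit mRNAs were lower in G2A liver (list median log2 fold change -0.21, with all 33 members below 0), and endoplasmic reticulum (ER) chaperone mRNAs were higher (median 0.41). Derl3, a membrane protein of the pathway that retrieves misfolded proteins from the ER for degradation, rose from 1.04 ± 0.478 to 28.6 ± 8.21 FPKM (SD, n = 3 livers per genotype), a log2 fold change of 3.85. Hypoxia and glycolysis genes (median 0.57) and extracellular matrix genes (median 0.58) were higher, and cell cycle genes (median -0.34) and heme synthesis genes (median -0.40) were lower. These list calls passed limma's camera test with a preset correlation between genes, and none of the 36 lists passed with an estimated correlation (smallest adjusted p = 0.397; 2 lists at an unadjusted p under 0.05). By fry, which tests whether a list's genes move on balance one way and compares it with no other genes, 8 lists passed: proteasome subunits, assembly factors and activators, ER-associated degradation, unfolded protein response, integrated stress response, autophagy and lysosome, hypoxia and glycolysis, and endothelial markers.

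Of 12938 genes tested with limma, 2 were higher and 1 was lower in G2A liver at an adjusted p under 0.05. Derl3 was higher in all 3 G2A livers, by 14.4-fold on the log2(FPKM + 1) scale (SE of the log2 fold change 0.24, adjusted p = 0.0106). Its call was lost without WT liver 1 (log2 fold change 3.74) and without WT liver 2 (3.77). It was also lost with the sample number as a replicate block (3.85, adjusted p = 0.0725). Mir142, a microRNA gene of blood cells, was listed at 0 in all 3 WT livers and at 386, 1192 and 402 FPKM in G2A livers 1, 2 and 3 (adjusted p = 0.00261). Snord53, a small nucleolar RNA gene, was listed at 512, 497 and 253 FPKM in the WT livers and at 0 in the 3 G2A livers (adjusted p = 0.00041). Both kinds of gene commonly lie within longer transcripts, whose reads these values do not separate. Small RNA genes took 16.8% to 21.7% of the FPKM of a liver library. At an unadjusted p under 0.05, 1173 genes were higher and 1598 lower. The groups did not overlap for 1533 genes that were higher and 2031 that were lower in G2A, together 27.5% of the genes. Averaged over all splits into 3 livers against 3 the share is 10%, and 1 split can lie far from it.

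G2A liver 3 stood apart from the other G2A livers. On the first principal component (37.9% of the variance) the WT livers lay at 13.3, 23.3 and 21.1, G2A livers 1 and 2 at -30.6 and -34.9, and G2A liver 3 at 7.91. Without G2A liver 3, 1604 genes were higher and 1548 lower. The counts of higher and lower genes were 1 and 1 without WT liver 1, 2 and 2 without WT liver 2, 3 and 1 without WT liver 3, 4 and 4 without G2A liver 1, and 2 and 4 without G2A liver 2. They were 3376 and 2681 with library weights estimated by limma, 4 and 1 with embryo sex in the model, and 1 and 0 without small RNA genes. The weights and the removal of small RNA genes were chosen after seeing the data.

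**Figure D1:**
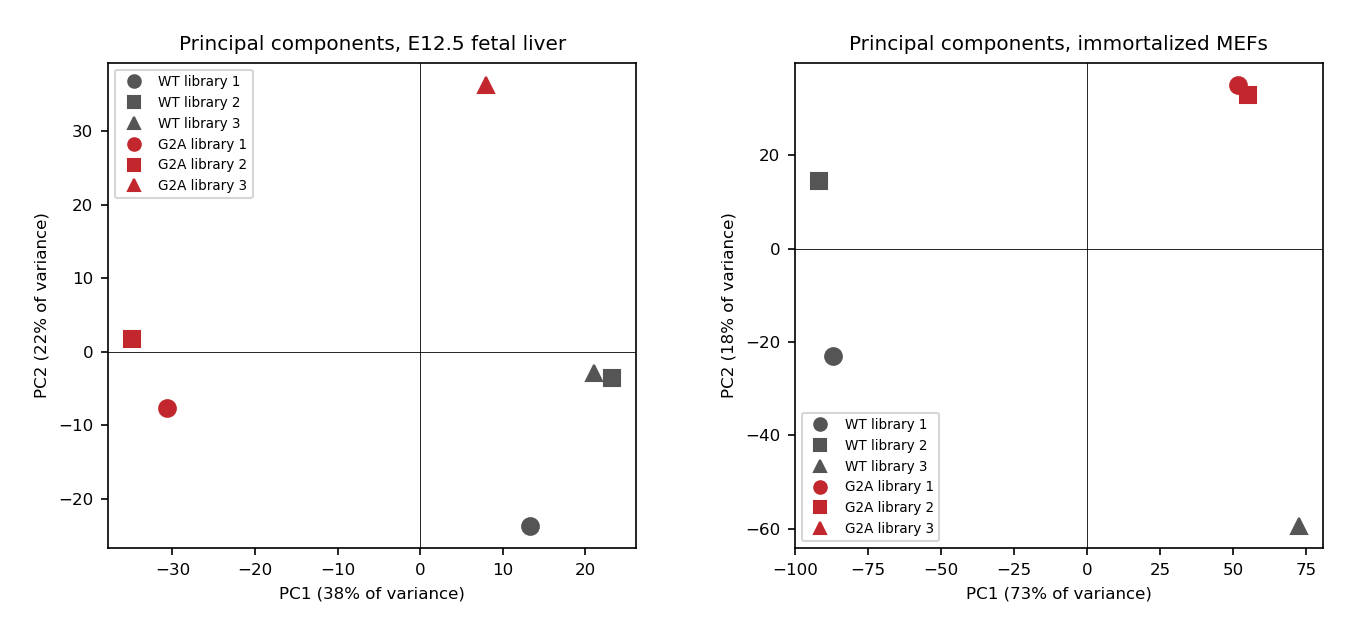
Principal components 1 and 2 of the log2 values, 1 point per library, for the livers (left) and the MEFs (right), with the percent of variance on each axis. G2A liver 3 lay at 7.91 on the first component of the livers, between the WT livers and the other G2A livers, and WT MEF 3 lay at 72.5 on that of the MEFs, on the side of the G2A MEFs.

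Genes with the next smallest p in each direction, not past the threshold, included Hspa1a, an inducible heat shock chaperone, at 0.476 ± 0.0917 FPKM in WT and 3.29 ± 0.548 in G2A liver (log2 fold change 1.53, adjusted p = 0.0609). Hmox1, a heme-degrading enzyme, was at 112 ± 3.90 and 171 ± 12.0 FPKM, and F13a1, a coagulation factor subunit, at 5.71 ± 0.462 and 11.1 ± 0.807. Cpa1, a carboxypeptidase, was at 4.35 ± 1.44 FPKM in WT and 0.435 ± 0.0982 in G2A liver. Mrps11, a mitochondrial ribosomal protein, was at 43.0 ± 1.24 and 30.5 ± 1.21, and Cenpm, a kinetochore protein, at 31.9 ± 1.37 and 22.0 ± 0.907. The adjusted p of each of the last 5 was 0.0811.

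Proteasome subunits were lower in G2A liver as a list (33 members tested, median log2 fold change -0.21, camera adjusted p = 1.7e-12, adjusted p = 0.397 with an estimated correlation). None of the 33 passed the test over all genes, 22 were lower adjusted over the list alone, and 27 were lower without overlap between the groups. The mean log2 level of the list lay 0.22, 0.25 and 0.11 below the WT mean in G2A livers 1, 2 and 3. Quantile normalization moved the median to -0.10 without ending the call. Psmd13, a subunit of the proteasome lid, was at 102 ± 4.04 FPKM in WT and 82.0 ± 4.58 in G2A liver (log2 fold change -0.31, adjusted p = 0.0977). Psmc3, another proteasome ATPase, was at 172 ± 5.23 and 138 ± 9.51 (-0.32, adjusted p = 0.0994). Psmc1, the gene that carries the allele (ENSMUSG00000021178.8, protein coding, plus strand of chromosome 12, positions 101348396 to 101361574 in NCBIM37, the assembly also called mm9), was at 179 ± 1.90 FPKM in WT and 152 ± 8.08 in G2A liver, n = 3 each. Its log2 fold change was -0.23 (SE 0.06, adjusted p = 0.114), and it was lower in all 3 G2A livers; without G2A liver 3 it passed the threshold at -0.27. Nmt1 and Nmt2, the N-myristoyltransferases, were at 90.2 and 16.0 FPKM in WT and at 80.5 and 15.1 in G2A liver, log2 fold changes of -0.16 and -0.07 (adjusted p = 0.252 and 0.561). Expression levels do not show the base change of the allele itself.

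Proteasome assembly factors and activators were also lower as a list (18 members, median -0.20, camera adjusted p = 0.000148, adjusted p = 0.397 with an estimated correlation), with 0 members past the test over all genes and 4 lower adjusted over the list alone. The list mean lay 0.19, 0.22 and 0.09 below the WT mean in G2A livers 1, 2 and 3, and quantile normalization moved the median to -0.13. Among its members, the assembly chaperone Psmg3 was at 33.7 ± 1.42 FPKM in WT and 23.3 ± 0.516 in G2A liver (log2 fold change -0.51, adjusted p = 0.0811), and Psmg1 at 49.7 and 42.4 (-0.22, adjusted p = 0.115). The immunoproteasome and MHC class I list did not pass (12 members, median 0.10, adjusted p = 0.356; 0 adjusted over the list alone). In that list Tap1, a peptide transporter, was at 1.5 and 4.2 FPKM and Psmb10, an immunoproteasome subunit, at 23.3 and 17.7 (adjusted p = 0.134 and 0.188).

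**Figure D2:**
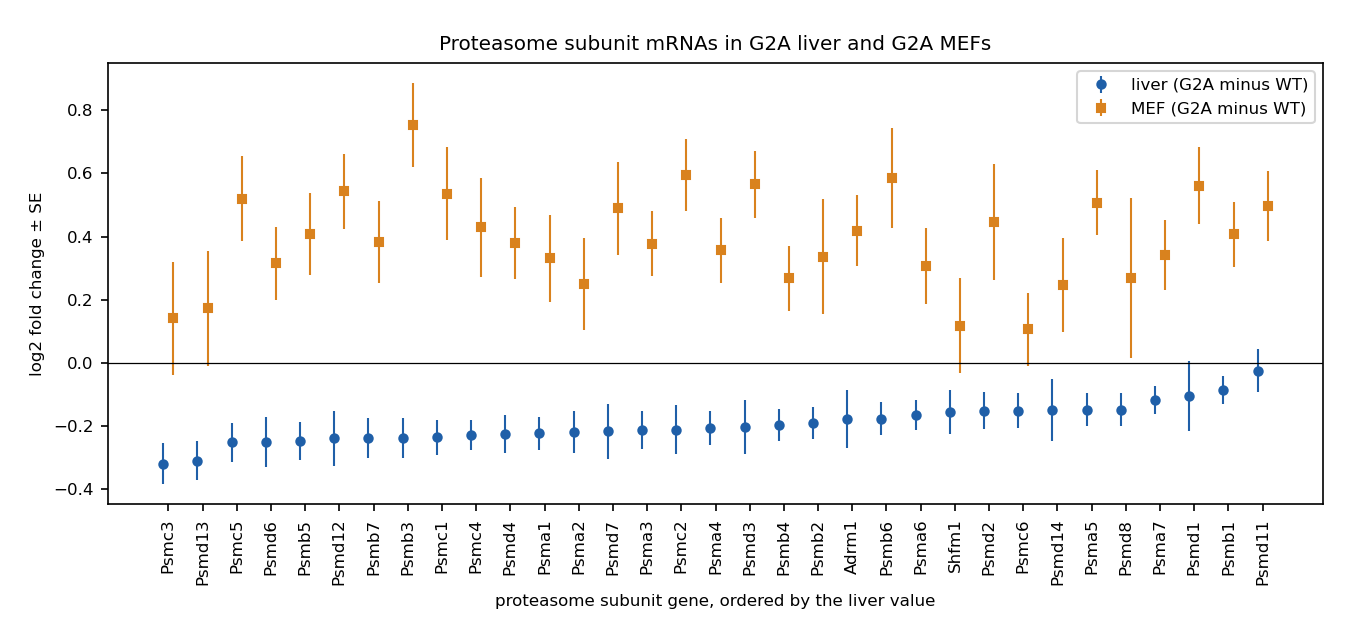
Log2 fold change (G2A minus WT) with its SE for each of the 33 proteasome subunit genes in liver (blue circles) and MEFs (orange squares), ordered by the liver value. The list medians were -0.21 in liver and 0.38 in MEFs.

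Chaperones of the unfolded protein response, which fold proteins in the ER, were higher in G2A liver (14 members, median log2 fold change 0.41, camera adjusted p = 5.86e-09, adjusted p = 0.397 with an estimated correlation). Over all genes 0 members passed, and 11 were higher adjusted over the list alone. The list mean was 0.35, 0.53 and 0.38 above the WT mean in G2A livers 1, 2 and 3, while the WT livers lay between -0.01 and 0.01. Creld2, a secreted ER stress protein, was at 35.6 ± 3.64 FPKM in WT and 91.6 ± 18.3 in G2A liver (log2 fold change 1.32). Hsp90b1, the ER chaperone Grp94, was at 392 ± 9.36 and 608 ± 52.0 (0.63), and the adjusted p of both was 0.0811. Integrated stress response genes, targets of the transcription factor Atf4, were higher as well (23 members, median 0.41, camera adjusted p = 0.000112, adjusted p = 0.397 with an estimated correlation). Of these, 0 passed over all genes and 11 were higher adjusted over the list alone. The mean of this list was 0.50, 0.62 and 0.29 above the WT mean in G2A livers 1, 2 and 3, and a stricter filter on low values moved the median to 0.27. Stc2, a secreted glycoprotein, was at 2.33 and 6.60 FPKM (log2 fold change 1.18, adjusted p = 0.0811), and Vldlr, a lipoprotein receptor, at 1.82 and 5.63 (1.21, adjusted p = 0.0902).

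ER-associated degradation genes were higher as a list (26 members, median log2 fold change 0.10, mean 0.24, camera adjusted p = 0.00937, adjusted p = 0.497 with an estimated correlation). Derl3 was the 1 member past the test over all genes, and 2 were higher adjusted over the list alone. The list mean was 0.23, 0.30 and 0.20 above the WT mean in G2A livers 1, 2 and 3; the call was lost without G2A liver 3 (median 0.11) and with library weights. Much of that rise was Derl3: without it, a choice made after seeing the data, the list mean was 0.09, 0.14 and 0.05 above the WT mean, and the call stood (median 0.09, adjusted p = 0.0375). With a trend on transcript length and GC content removed, a test chosen after seeing the data, the median was 0.06 and the call stood. Autophagy and lysosome genes were higher (19 members, median 0.15, camera adjusted p = 0.00157, adjusted p = 0.397 with an estimated correlation). Over all genes none passed, and 9 were higher adjusted over the list alone. Their list mean was 0.12, 0.20 and 0.14 above the WT mean in G2A livers 1, 2 and 3, and library weights ended the call. Lamp2, a lysosomal membrane protein, was at 46.3 and 60.3 FPKM and Ctsl, a lysosomal protease, at 76.1 and 100.2 (adjusted p = 0.0902 for both). The p53 targets were higher (23 members, median 0.12, camera adjusted p = 0.0173, adjusted p = 0.397 with an estimated correlation). No p53 target passed over all genes, and 2 were higher adjusted over the list alone. The p53 mean was 0.23, 0.29 and 0.13 above the WT mean in G2A livers 1, 2 and 3, and the call was lost without G2A liver 3 (median 0.16), with a stricter filter (0.07) and with library weights. Perp, a membrane protein linked to cell death, was at 4.60 and 12.8 FPKM and Fas, a death receptor, at 1.13 and 3.71 (adjusted p = 0.0902 and 0.101).

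The heat shock list did not pass (19 members, median log2 fold change -0.12, mean 0.27, camera direction down, adjusted p = 0.969), with 4 members higher and 2 lower adjusted over the list alone. Hspa1b, like Hspa1a an inducible heat shock chaperone, was at 0.40 FPKM in WT and 2.45 in G2A liver (log2 fold change 1.28, adjusted p = 0.0811). The NRF2 list did not pass either (17 members, median -0.13, mean 0.04, camera direction down, adjusted p = 0.747; 3 higher adjusted over the list alone). In it Me1, malic enzyme, was at 5.09 and 16.3 FPKM (log2 fold change 1.51, adjusted p = 0.0811). The interferon list had a median of -0.15 (16 members, adjusted p = 0.9; 1 higher adjusted over the list alone). It held the chemokine Cxcl10 at 8.14 and 23.2 FPKM and Ifi35 at 21.5 and 13.7 (adjusted p = 0.0902 and 0.173). The cholesterol synthesis list had a median of -0.03 (24 members, adjusted p = 0.856; 0 adjusted over the list alone), with a log2 fold change of 0.26 for Sc5d, an enzyme of a late step (adjusted p = 0.148).

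Hypoxia and glycolysis genes were higher in G2A liver (23 members, all above 0, median log2 fold change 0.57, camera adjusted p = 1.7e-12, adjusted p = 0.397 with an estimated correlation). Over all genes 0 members passed, and 18 were higher adjusted over the list alone. The list mean was 0.72, 0.78 and 0.45 above the WT mean in G2A livers 1, 2 and 3. Ero1l, an oxidase of the ER, was at 30.5 ± 3.44 FPKM in WT and 55.9 ± 6.88 in G2A liver (log2 fold change 0.85). Pgk1, a glycolytic kinase, was at 385 ± 60.4 and 663 ± 29.0 (0.79), both with an adjusted p of 0.0902. Cell cycle genes were lower (28 members, 27 below 0, median -0.34, camera adjusted p = 3.08e-12, adjusted p = 0.497 with an estimated correlation), with 0 past the test over all genes and 23 lower adjusted over the list alone. Their list mean lay 0.34, 0.43 and 0.15 below the WT mean in G2A livers 1, 2 and 3. Red cell lists were likewise furthest below it in G2A livers 1 and 2, and the share of dividing red cells was not separated from a change within cells. Cdk1, the mitotic kinase, was at 76.7 ± 0.497 and 63.2 ± 1.58 FPKM (log2 fold change -0.28), and Birc5, a mitotic regulator, at 256 ± 3.09 and 190.3 ± 17.8 (-0.43), both with an adjusted p of 0.0902.

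Red cell genes differed between G2A liver 3 and the other G2A livers. The erythroid list was lower in G2A liver (25 members, 23 below 0, median log2 fold change -0.43, camera adjusted p = 8.46e-05, adjusted p = 0.664 with an estimated correlation). No erythroid gene passed over all genes or adjusted over the list alone. Its mean lay 0.60 and 0.76 below the WT mean in G2A livers 1 and 2 and 0.08 above it in G2A liver 3; the median was -0.66 without G2A liver 3 and -0.25 without G2A liver 2. Epor, the erythropoietin receptor, was at 96.1 ± 2.57 FPKM in WT and 69.2 ± 10.4 in G2A liver (adjusted p = 0.107), and Klf1, an erythroid transcription factor, at 255 ± 17.7 and 163 ± 57.0 (adjusted p = 0.163). Heme synthesis genes were lower (12 members, all below 0, median -0.40, camera adjusted p = 6.33e-05, adjusted p = 0.521 with an estimated correlation), with 0 past the test over all genes and 2 lower adjusted over the list alone. Their list mean lay 0.52, 0.74 and 0.08 below the WT mean in G2A livers 1, 2 and 3, and the median was -0.63 without G2A liver 3 and -0.27 without G2A liver 2. Tmem14c and Slc25a38, mitochondrial proteins of this pathway, were at 449 and 73.9 FPKM in WT and at 309 and 53.5 in G2A liver (adjusted p = 0.0902 and 0.0914).

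The embryonic globins of primitive red cells were higher as a list (3 members, median log2 fold change 1.18, camera adjusted p = 0.049, adjusted p = 0.622 with an estimated correlation). No globin of the list passed over all genes or adjusted over the list alone. The near-identical adult alpha globins Hba-a1 and Hba-a2 share reads, so their separate values are uncertain, and only their sum entered the ratio of primitive to adult globins. Hbb-y was at 11145 ± 3391 FPKM in WT and 26566 ± 11841 in G2A liver (adjusted p = 0.17), and Hba-x at 6228 ± 2857 and 17821 ± 9505 (adjusted p = 0.2). The list mean was 1.52, 1.81 and 0.14 above the WT mean in G2A livers 1, 2 and 3 and lay at -0.17, 0.54 and -0.38 in the WT livers. The call was lost without WT liver 1 (median 1.07), WT liver 3 (1.06), G2A liver 1 (1.09) or G2A liver 2 (0.87), and with a pseudocount of 0.1, without a filter or without a variance trend. The ratio of summed primitive to summed adult globin FPKM was 0.443, 1.31 and 0.406 in the WT livers and 3.40, 5.21 and 0.677 in G2A livers 1, 2 and 3.

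**Figure D3:**
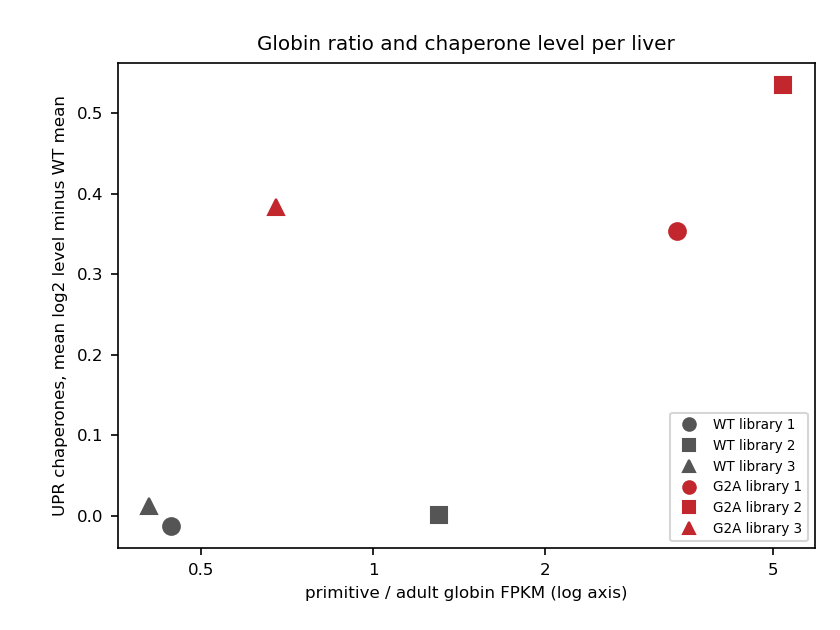
Mean log2 level of the unfolded protein response chaperones minus the WT mean, against the ratio of primitive to adult globin FPKM (log axis), 1 point per liver. G2A liver 3 had a chaperone level 0.38 above the WT mean at a globin ratio of 0.677, and WT liver 2 had a level at the WT mean at a ratio of 1.31.

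Stromal and vascular genes were higher in G2A liver. Extracellular matrix genes (28 members, 27 above 0, median log2 fold change 0.58, camera adjusted p = 1.37e-09, adjusted p = 0.521 with an estimated correlation) had 0 members past the test over all genes and 15 higher adjusted over the list alone. Fn1, fibronectin, was at 90.7 ± 3.90 FPKM in WT and 149.9 ± 20.1 in G2A liver (log2 fold change 0.71). Lum, a matrix proteoglycan, was at 58.3 ± 12.8 and 184 ± 60.2 (1.61), and Postn, periostin, at 37.5 ± 14.4 and 203 ± 95.8 (2.36), each with an adjusted p of 0.0902. The matrix list mean was 0.69, 0.995 and 0.38 above the WT mean in G2A livers 1, 2 and 3, against 0.22, -0.27 and 0.05 in the WT livers. Another split gave this list, like others, a smaller unadjusted camera p (3.43e-16 against 1.53e-10). Markers of liver mesenchyme and mesothelium, 10 of 18 of which stand in another list, were higher (median 0.34, camera adjusted p = 0.000111, adjusted p = 0.521 with an estimated correlation). None passed over all genes and 8 were higher adjusted over the list alone. Their mean was 0.73, 1.04 and 0.30 above the WT mean in G2A livers 1, 2 and 3, and the median was 0.52 without G2A liver 3 and 0.56 with library weights. Endothelial markers were higher (18 members, median 0.20, camera adjusted p = 0.00232, adjusted p = 0.397 with an estimated correlation). No endothelial marker passed over all genes and 3 were higher adjusted over the list alone, with list means of 0.21, 0.23 and 0.15 above the WT mean. Kdr and Flt1, receptors for vascular endothelial growth factor, were at 13.6 and 2.96 FPKM in WT and 19.2 and 5.68 in G2A liver (adjusted p = 0.0914 and 0.107).

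Receptor tyrosine kinases were higher as a list (30 members, 29 above 0, median log2 fold change 0.23, camera adjusted p = 0.000195, adjusted p = 0.664 with an estimated correlation). Over all genes no kinase passed, and 1 was higher adjusted over the list alone. The kinase mean was 0.42 and 0.47 above the WT mean in G2A livers 1 and 2 and lay at -0.15 in G2A liver 3. Hox genes ran alike (0.76, 0.63 and -0.35). A differing make-up of the liver samples was not separated from a change within cells. The median was 0.49 without G2A liver 3 and 0.15 without G2A liver 2, and 0.49 with library weights. It was 0.14 with the trend on transcript length and GC content removed, and the call stood. Integrins and adhesion molecules were higher (25 members, median 0.12, camera adjusted p = 0.042, adjusted p = 0.64 with an estimated correlation). No integrin or adhesion gene passed over all genes or adjusted over the list alone. The integrin mean was 0.14, 0.25 and 0.02 above the WT mean in G2A livers 1, 2 and 3. The integrin call was lost without WT liver 2 (median 0.09), WT liver 3 (0.10), G2A liver 2 (0.12) or G2A liver 3 (0.15), with embryo sex in the model and with library weights, and the median was 0.18 without WT liver 1. Removing that trend moved the integrin median to 0.05 and ended the call (adjusted p = 0.114). Itgb1, the common integrin beta chain, was at 106 and 138 FPKM (adjusted p = 0.13), and Icam1, an adhesion molecule, had a log2 fold change of 0.30 (adjusted p = 0.164). Epithelial markers were higher (11 members, all above 0, median 0.63, camera adjusted p = 0.00308, adjusted p = 0.664 with an estimated correlation). No epithelial marker passed over all genes or adjusted over the list alone. The epithelial mean was 0.83 and 1.67 above the WT mean in G2A livers 1 and 2 and lay at -0.16 in G2A liver 3. The median was 1.14 without G2A liver 3 and 0.27 without G2A liver 2. Cldn4 and Krt19, a tight junction protein and a keratin of ducts, were at 2.55 and 11.1 FPKM in WT and 12.9 and 30.4 in G2A liver (adjusted p = 0.144 and 0.198).

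Neural markers were lower in G2A liver (7 members, median log2 fold change -0.94, camera adjusted p = 0.0408, adjusted p = 0.622 with an estimated correlation), with 0 past the test over all genes and 0 adjusted over the list alone. Their list mean lay at -0.70, -0.29 and -1.23 in G2A livers 1, 2 and 3. The call was lost without WT liver 1 (median -0.74) or G2A liver 3 (-0.56), with a stricter filter (-0.71), a pseudocount of 0.1 (-1.26), embryo sex in the model (-0.78) and library weights (-0.87). Sox10, a neural crest factor, was at 3.51 FPKM in WT and 1.03 in G2A liver, and Tubb3, a neuronal tubulin, at 7.91 and 2.88 (adjusted p = 0.138 and 0.203).

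The other lists did not pass camera in liver. Hepatoblast markers had a median log2 fold change of -0.01 (28 members, adjusted p = 0.921), with Dlk1 at 0.25 and Krt8 at 0.84 (adjusted p = 0.152 and 0.207). Haematopoietic progenitor markers had a median of 0.01 (14 members, adjusted p = 0.9), with Lmo2 at -0.41 and Cd34 at 0.26 (adjusted p = 0.251 and 0.339). Macrophage and myeloid markers had a median of -0.0025 (20 members, adjusted p = 0.994), with Cd68 at 0.31 and Mrc1 at 0.22 (adjusted p = 0.145 and 0.222). Megakaryocyte markers had a median of 0.13 (11 members, adjusted p = 0.0905), with Vwf at 6.49 and 10.3 FPKM and Itgb3 at a log2 fold change of 0.23 (adjusted p = 0.103 and 0.403). Smooth muscle markers had a median of -0.08 (8 members, adjusted p = 0.655), with Myh11 at -0.99 and Cnn1 at -0.72 (adjusted p = 0.208 and 0.546). Skeletal muscle markers had a median of 0.23 and a mean of 0.09 with camera direction down (8 members, adjusted p = 0.9), and held Mylpf at -0.44 and Myog at -0.57 (adjusted p = 0.318 and 0.464). Adipocyte markers had a median of 0.21 (5 members, adjusted p = 0.0905), with Fabp4 at 0.92 and Cd36 at 0.53 (adjusted p = 0.103 and 0.186). Cartilage and bone markers had a median of -0.10 (5 members, adjusted p = 0.593), with Spp1 at -0.996 and Sox9 at 0.55 (adjusted p = 0.156 and 0.411). Among signalling lists, inflammatory secretory factors had a median of 0.03 (8 members, adjusted p = 0.746), with the chemokine Ccl2 at 1.05 (adjusted p = 0.124). Developmental signalling targets had a median of 0.15 (18 members, adjusted p = 0.0632), with the Wnt pathway genes Lef1 at 0.74 and Nkd1 at 0.76 (adjusted p = 0.0902 and 0.168). Hox genes, which mark position along the body, had a median of 0.11 (25 members, adjusted p = 0.125), with Hoxc10 at 1.91 and Hoxa10 at 1.86 (adjusted p = 0.0902 and 0.0994). Of these lists, inflammatory factors had 2 members higher and 2 lower adjusted over the list alone, Hox genes 4 higher, developmental targets, megakaryocytes and adipocytes 1 higher each, and the rest 0. With the length and GC trend removed, developmental targets (0.19), Hox genes (0.12) and megakaryocyte markers (0.14) passed as higher at the preset correlation. With the trend kept, G2A liver 3 lay below all WT livers for developmental targets (-0.15) and Hox genes (-0.35). For megakaryocytes G2A livers 1 and 2 lay below WT liver 2. By Xist and Y-linked reads, WT livers 2 and 3 and G2A liver 2 were female and the others male. The embryo sex list had an adjusted p of 0.609.

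**Figure D4:**
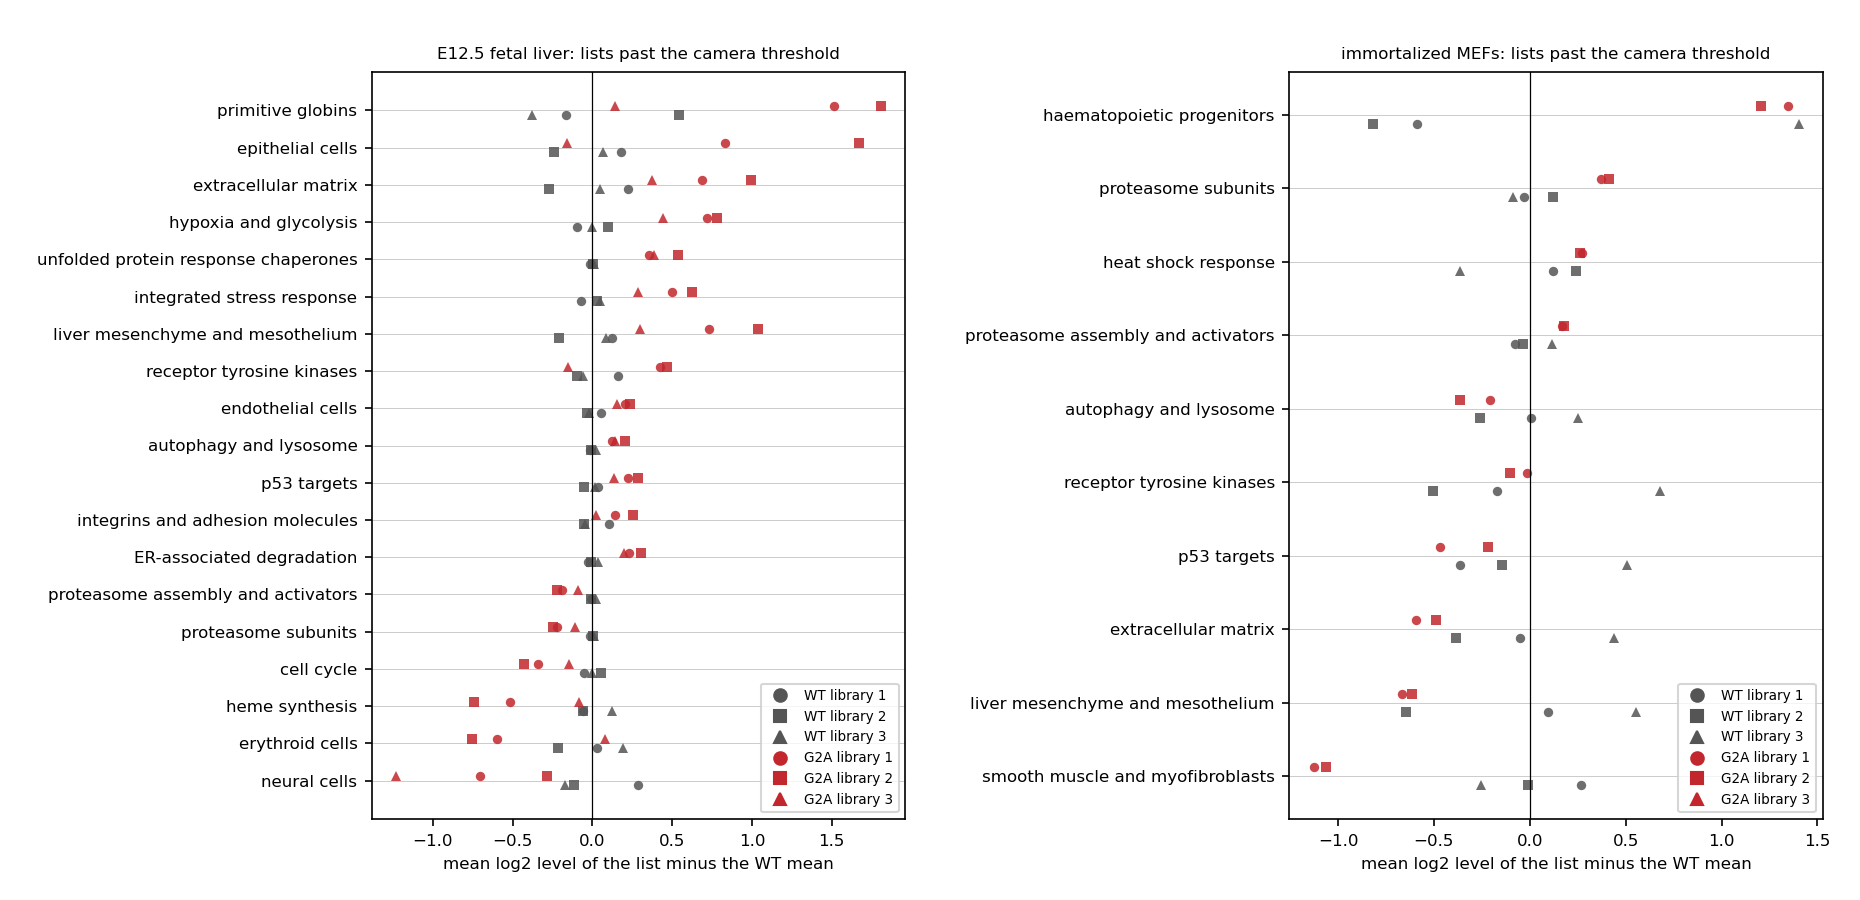
Mean log2 level of each list past the camera threshold, minus the WT mean of that list, 1 point per library, in liver (left, 19 lists) and MEFs (right, 10 lists). In liver the G2A values of the chaperone list lay between 0.35 and 0.53, above all WT livers, while the erythroid mean of G2A liver 3 lay at 0.08.

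The second comparison asked the same question in immortalized MEFs. Proteasome subunit mRNAs were higher in G2A MEFs (list median log2 fold change 0.38, with all 33 members above 0), and extracellular matrix (median -0.62) and smooth muscle (median -1.07) genes were lower, by camera with a preset correlation. Mmp2, a matrix-degrading protease, was at 3423 ± 803 normalized reads in WT (SD, n = 3) and 323 ± 29.2 in G2A MEFs (n = 2), and Psmb3, a subunit of the proteolytic core, at 4884 ± 583 and 8194 ± 113. No single gene passed limma's threshold. With an estimated correlation 0 of 35 lists passed, and the adjusted p of each of the 10 called lists was 0.748; 1 list had an unadjusted p under 0.05. By fry 0 lists passed (smallest adjusted p = 0.0954).

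Of 13241 genes tested in MEFs with limma, 0 were higher and 0 lower at an adjusted p under 0.05 (smallest 0.127), while 913 were higher and 990 lower at an unadjusted p under 0.05. On the recovered reads edgeR gave 0 and 0, and DESeq2 gave 374 higher and 627 lower; both were chosen after seeing the data. The groups did not overlap for 2496 genes that were higher and 2383 that were lower in G2A, together 36.8% of the genes. Averaged over all splits into 3 libraries against 2 the share is 20%, and 1 split can lie far from it. WT MEF 3 stood apart: its log2 values correlated across genes with r of 0.953 and 0.958 with G2A MEFs 1 and 2, and 0.890 and 0.882 with WT MEFs 1 and 2, which correlated at 0.984 with each other. Without WT MEF 3, 1550 genes were higher and 1525 lower by limma, and 1556 and 1666 by edgeR; with any other library left out, limma called 0. With library weights the counts were 3149 and 2975, and with the sex of the line in the model 212 and 245. In the fits without WT MEF 3, genotype cannot be told apart from sex and Hox pattern (Xist and Hoxd13, under other observations).

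The genes with the smallest p, of which none passed, were led by Mmp2 (log2 fold change -3.38, adjusted p = 0.127) and Tgfb2, a growth factor, at 3163 ± 380 and 822 ± 9.09 normalized reads (-1.94, adjusted p = 0.127). Unc5c, a netrin receptor, was at 2973 ± 876 and 318 ± 34.1 (-3.19, adjusted p = 0.165). Ednrb, an endothelin receptor, was at 798 ± 95.6 and 172 ± 18.1, and Plagl1, an imprinted zinc finger factor, at 4411 ± 820.2 and 953 ± 159 (adjusted p = 0.21 for both). With higher G2A values, Rhob, a small GTPase, was at 6715 ± 131 and 11969.7 ± 519. Dock8, a guanine exchange factor, was at 251 ± 31.7 and 931 ± 251, and Etv4, a transcription factor of the ETS family, at 1269 ± 171 and 2812 ± 288. C3ar1, a complement receptor, was at 4.52 ± 4.23 and 261 ± 25.3, and Mcpt8, a mast cell protease, at 6.39 ± 2.71 and 157 ± 12.6. The adjusted p of these last 5 was 0.26. Psmc1 was at 7489 ± 1056 normalized reads in WT and 10786 ± 180.3 in G2A MEFs (log2 fold change 0.54, SE 0.15, adjusted p = 0.282), higher in both G2A MEFs. It passed the threshold with DESeq2 (0.53) and without WT MEF 3 (0.44), where genotype cannot be told apart from sex and Hox pattern. Nmt1 and Nmt2 were at 4740.3 and 4528 in WT and 6939 and 7317 in G2A MEFs, log2 fold changes of 0.55 and 0.69 (adjusted p = 0.269 for both).

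Proteasome subunits were higher as a list in G2A MEFs (33 members, median log2 fold change 0.38, camera adjusted p = 1.03e-13, adjusted p = 0.748 with an estimated correlation). In limma 0 members passed over all genes, 18 were higher adjusted over the list alone, and 27 were higher without overlap. The list mean was 0.37 and 0.41 above the WT mean in G2A MEFs 1 and 2 and lay at -0.03, 0.12 and -0.09 in WT MEFs 1, 2 and 3. Psmd3, a subunit of the proteasome lid, was at 9104 ± 475 and 13461 ± 95.4 normalized reads (log2 fold change 0.57, adjusted p = 0.269), beside Psmb3 (0.75, adjusted p = 0.269). Assembly factors and activators were higher (18 members, median 0.26, camera adjusted p = 0.0162, adjusted p = 0.748 with an estimated correlation), with 0 past the test over all genes and 0 adjusted over the list alone. Their list mean was 0.17 and 0.18 above the WT mean in G2A MEFs 1 and 2 and 0.12 in WT MEF 3, and the call was lost with the sex of the line in the model (median 0.21). It was also lost with the trend on transcript length and GC content removed (median 0.20, adjusted p = 0.0557). Psmd9, an assembly chaperone, was at 1654 and 2166 normalized reads and Pomp, the maturation protein of the proteasome core, at 3237 and 4232 (adjusted p = 0.277 and 0.298).

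Matrix and contractile genes were lower in G2A MEFs. The extracellular matrix list (29 members, median log2 fold change -0.62, camera adjusted p = 6.12e-05, adjusted p = 0.748 with an estimated correlation) had 0 members past the test over all genes and 8 lower adjusted over the list alone. Its mean lay 0.59 and 0.49 below the WT mean in G2A MEFs 1 and 2, against -0.05, -0.39 and 0.44 in WT MEFs 1, 2 and 3. Col6a3, a collagen chain, was at 19691 ± 6568 and 5195 ± 903 normalized reads (-1.87). Markers of liver mesenchyme and mesothelium, which share 6 collagen and other matrix genes with that list, were lower (13 members, median -1.04, camera adjusted p = 0.0225, adjusted p = 0.748 with an estimated correlation). None passed over all genes, and 1 was higher and 6 lower adjusted over the list alone. Their list mean lay at -0.67 and -0.62 in the G2A MEFs and at 0.09, -0.65 and 0.55 in WT MEFs 1, 2 and 3. The call was lost without WT MEF 3 (median -1.15), without a filter (-0.57) and with library weights (-1.27). Col3a1, another collagen chain, was at 49035 ± 26107 and 9488 ± 105, and Pdgfrb, a growth factor receptor of stromal cells, at 13430.1 and 6254. Smooth muscle and myofibroblast markers were lower (9 members, median -1.07, camera adjusted p = 0.0162, adjusted p = 0.748 with an estimated correlation), with 0 past the test over all genes and 1 lower adjusted over the list alone. Their list mean lay at -1.13 and -1.06 in the G2A MEFs and at 0.27, -0.01 and -0.26 in WT MEFs 1, 2 and 3, and the call was lost with the sex of the line in the model (median -0.40). Actg2 and Acta2, smooth muscle actins, were at 5019 ± 2726 and 195851 ± 50299 normalized reads in WT and 342 ± 69.5 and 91224 ± 3355 in G2A MEFs (adjusted p = 0.269 and 0.3).

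In most of the 5 remaining called lists WT MEF 3 lay apart from WT MEFs 1 and 2. With an estimated correlation the adjusted p of all 5 was 0.748. Heat shock genes were higher in G2A MEFs (19 members, median log2 fold change 0.37, camera adjusted p = 0.0296). Their means were 0.27 and 0.26 in the G2A MEFs and 0.12, 0.24 and -0.36 in WT MEFs 1, 2 and 3. The heat shock call was lost without WT MEF 3 (median 0.16), without G2A MEF 2 (0.34) and with library weights, and Hspa4, a cytosolic chaperone, was at 12888 and 16673 normalized reads. Haematopoietic progenitor markers were higher (9 members, median 1.28, camera adjusted p = 0.0157). Their means were 1.35 and 1.21 in the G2A MEFs and -0.59, -0.82 and 1.40 in the WT MEFs. That median was 2.09 without WT MEF 3 and 0.82 without a filter, the call was lost without WT MEF 2 (0.79), and with the sex of the line in the model the test turned direction (0.05). Its member Ly6a, the surface antigen Sca-1, was at 1004 ± 225 and 2473 ± 869. The p53 targets were lower (25 members, median -0.26, camera adjusted p = 0.012). Their means were -0.47 and -0.22 in the G2A MEFs and -0.36, -0.14 and 0.51 in the WT MEFs. Their call was lost without WT MEF 3 (median -0.10) and with library weights (-0.09), and the median was -0.78 with the sex of the line in the model. Perp was at 260.5 and 103 normalized reads and Fas at 239 and 83.5. Autophagy and lysosome genes were lower (20 members, median -0.14, camera adjusted p = 0.0384). Their means were -0.21 and -0.36 in the G2A MEFs and 0.01, -0.26 and 0.25 in the WT MEFs. This call was lost without WT MEF 3 (median -0.06), without G2A MEF 2 (-0.11), with quantile normalization, with library weights and without a variance trend, and the median was -0.25 without WT MEF 2 and -0.29 without G2A MEF 1. Over the 19 members with a known length the call was lost (median -0.13, adjusted p = 0.0534), and it stood with the length and GC trend removed (-0.21). Ctsd, a lysosomal protease, was at 21158 ± 992 and 14899 ± 296. Receptor tyrosine kinases were lower (29 members, median -0.18, camera adjusted p = 0.0338). Their means were -0.01 and -0.10 in the G2A MEFs and -0.17, -0.50 and 0.68 in the WT MEFs. The call was lost without WT MEF 3 (median -0.04), without G2A MEF 2 (-0.21), without a variance trend and with library weights (-0.12), and the median was -0.29 without WT MEF 1. Fgfr2, a fibroblast growth factor receptor, was at 4689.6 ± 1456 and 1373 ± 82.6. In these 5 lists 0 members passed over all genes; adjusted over the list alone, 2 progenitor markers were higher, 6 receptor tyrosine kinases were lower, and the other 3 lists had 0. The replicate block, in which WT MEF 3 has no partner, ended the calls of heat shock, p53, autophagy, kinase and liver mesenchyme genes. With the sex of the line in the model the medians of heat shock, autophagy and kinase genes were 0.57, -0.43 and -0.74.

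Among the 25 lists that did not pass in MEFs, several took values in WT MEF 3 far from the other libraries. The mean of the interferon list was 4.09 above the WT mean in WT MEF 3 and its median log2 fold change was -1.19 (20 members, adjusted p = 0.091). The immunoproteasome list, at 2.30 in WT MEF 3, had a median of -0.93 (11 members, adjusted p = 0.2), and the cholesterol synthesis list, at -1.04 in WT MEF 3, had a median of -0.26 (25 members, adjusted p = 0.208). The Hox list had a median of 1.47 (30 members, adjusted p = 0.0547) and means of -0.89, -0.93 and 1.82 in WT MEFs 1, 2 and 3 and 2.08 and 1.89 in the G2A MEFs. The embryo sex list had a median of -4.68 (5 members, adjusted p = 0.362). Stress lists had medians of -0.19 for the integrated stress response (24 members, adjusted p = 0.0583; 2 lower adjusted over the list alone) and -0.13 for unfolded protein response chaperones (14 members, adjusted p = 0.2). With the length and GC trend removed both lists passed as lower at the preset correlation, at -0.24 (adjusted p = 0.0199) and -0.18 (adjusted p = 0.0471). With the trend kept, the former had G2A MEF 1 (0.01) above WT MEFs 1 and 2. The latter had WT MEF 3 (-0.12) between the G2A MEFs. Medians were -0.06 for ER-associated degradation (26 members, adjusted p = 0.343) and 0.20 for NRF2 targets (17 members, adjusted p = 0.122). In them Trib3, a stress-induced pseudokinase, was at 1160.1 and 404 normalized reads, and Atf5, a stress transcription factor, at 3657 and 1514. Hspa5, the ER chaperone BiP, was at 34461 ± 703 and 25132 ± 1765, and Sdf2l1, a cofactor of ER chaperones, at 625 and 784. Of the degradation genes, Nploc4, a cofactor of the Vcp segregase, was at 5162 and 7280.4 and Edem3, a mannosidase-like protein, at 2957 and 1849. Of the NRF2 targets, Nqo1, a quinone reductase, was at 898 and 1585.

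Further medians in MEFs were 0.13 for hypoxia and glycolysis (22 members, mean 0.05, camera direction down, adjusted p = 0.873) and 0.13 for cell cycle (28 members, adjusted p = 0.2). The median was 0.35 for integrins and adhesion (27 members, adjusted p = 0.343) and -0.15 for inflammatory factors (16 members, adjusted p = 0.532). Developmental signalling targets had a median of -0.29 (16 members, adjusted p = 0.2; 1 higher and 3 lower adjusted over the list alone) and endothelial markers of -0.49 (12 members, adjusted p = 0.2; 2 lower adjusted over the list alone). It was 0.06 for erythroid (9 members, adjusted p = 0.537), 0.26 for heme synthesis (12 members, adjusted p = 0.254), 0.23 for macrophage (4 members, adjusted p = 0.475) and 0.26 for megakaryocyte genes (5 members, adjusted p = 0.947). Hepatoblast markers had a median of -0.36 and a mean of 0.21 with camera direction up (20 members, adjusted p = 0.989), and skeletal muscle markers a median of 0.04 and a mean of -0.04 with camera direction down (3 members, adjusted p = 0.947). Medians were -0.48 for adipocyte (7 members, adjusted p = 0.831; 1 lower adjusted over the list alone) and -0.24 for cartilage and bone markers (6 members, adjusted p = 0.538). They were 0.95 for epithelial (6 members, adjusted p = 0.427; 2 higher adjusted over the list alone) and -0.71 for neural markers (6 members, adjusted p = 0.989; 2 higher adjusted over the list alone). The other MEF lists that did not pass had 0 members adjusted over the list alone. Tubb3 was at 153 and 529.6 normalized reads, Flt1 at 376 and 140.2, and Krt18, an epithelial keratin also among the hepatoblast markers, at 9.50 and 186; Cebpa, a hepatoblast factor, was at 189.9 and 31.5.

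The third comparison asked whether the G2A effect differed between liver and MEFs. Of 10818 genes in both tissues, 239 differed at an adjusted p under 0.05 (2556 at an unadjusted p under 0.05). The effect on proteasome subunits was lower in liver than in MEFs (median difference, liver minus MEF, -0.59 on the log2 scale, camera adjusted p = 4.14e-17). The effect on unfolded protein response chaperones (0.50, adjusted p = 2.45e-05) and extracellular matrix genes (1.14, adjusted p = 4.78e-10) was higher. Derl3 had the log2 fold change 3.85 in liver and -0.30 in MEFs, a difference of 4.15 (SE 0.59, adjusted p = 0.0337). For the difference of lists camera was run with the preset correlation alone.

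Among the genes past the threshold, the largest differences above 0 were those of Cox6a2, a muscle form of a respiratory chain subunit (4.68, adjusted p = 0.0404), Ppap2b, a lipid phosphatase (4.58, adjusted p = 0.0382), Derl3, Angpt1, an angiopoietin (4.08, adjusted p = 0.0446), and Epha3, an ephrin receptor (3.98, adjusted p = 0.0105). The largest below 0 among them were those of Snord53 (-8.11, adjusted p = 0.00956), C3ar1 (-5.48, adjusted p = 0.0382), Tubb3 (-3.20, adjusted p = 0.0382), Amacr, a racemase of branched fatty acid breakdown (-1.92, adjusted p = 0.0406), and Dock8 (-1.82, adjusted p = 0.0337). Each of these 10 calls was lost without G2A MEF 1 and without G2A MEF 2, with differences that stayed near those above (3.83 and 4.47 for Derl3, 4.68 and 4.67 for Cox6a2). Without WT MEF 1 all but that of Ppap2b were lost, without a filter all but those of Epha3 and Snord53, and without a variance trend all but those of Derl3, Epha3 and Snord53. Leaving out single livers never ended the calls of Epha3 and Snord53 and ended each of the others at least once. The count of 239 became 2 without either G2A MEF, 11 without WT MEF 1, 496 without WT MEF 2 and 3260 without WT MEF 3. It became 160 without WT liver 1, 60 without WT liver 2, 45 without WT liver 3, 50 without G2A liver 1, 35 without G2A liver 2 and 948 without G2A liver 3. By setting it was 29 without a filter, 19 without a variance trend, 152 with embryo sex and 2396 with the sex of the line in the model. It was 6151 with library weights, 1429 with DESeq2 and 3235 with edgeR without WT MEF 3. In the fits without WT MEF 3, genotype cannot be told apart from the sex and Hox pattern of the MEFs.

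Across genes, the liver and MEF log2 fold changes had a Pearson r of -0.04 and a Spearman rho of -0.22, and 39.4% of genes had the same sign. Genes are not independent replicates, and r was 0.021 without WT MEF 3. The log2 fold changes followed transcript length in opposite directions, with a Spearman rho of 0.27 in liver and -0.19 in MEFs. With the length and GC trend removed in each tissue, rho between the tissues was -0.18 and r was -0.02 over 10463 genes, against -0.23 and -0.04 for these genes before. At an unadjusted p under 0.05, 48 genes were higher in G2A in both tissues, against 70.3 for independent lists, and 24 were lower in both, against 103. By 1-sided Fisher exact tests the overlap was not above that of independent lists (p = 0.999 for higher and 1 for lower). At an adjusted p under 0.05 no gene was called in both tissues, as limma called 0 MEF genes.

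Of 35 lists, 14 differed between liver and MEFs. Below 0, with the effect lower in liver, were proteasome subunits (-0.59, with 29 of 33 members at an unadjusted p under 0.05), assembly factors and activators (-0.39, adjusted p = 0.000652), cell cycle (-0.38, adjusted p = 4.07e-05) and heme synthesis (-0.55, adjusted p = 0.00341). So were haematopoietic progenitors (-1.41, adjusted p = 0.0276) and Hox genes (-3.69, adjusted p = 0.0426). Above 0 were unfolded protein response chaperones, the integrated stress response (0.46, adjusted p = 0.00214), p53 targets (0.31, adjusted p = 0.000652) and autophagy and lysosome (0.27, adjusted p = 0.00341). Further lists above 0 were hypoxia and glycolysis (0.57, adjusted p = 0.000214), receptor tyrosine kinases (0.46, adjusted p = 0.00252), extracellular matrix, and liver mesenchyme and mesothelium (1.45, adjusted p = 0.000725). The Hox call was lost without WT liver 1 (-3.55), G2A liver 3 (-3.30), WT MEF 1 (-2.66), WT MEF 2 (-2.42) or G2A MEF 2 (-3.63), and the median was -5.59 without WT MEF 3. The progenitor call was lost without WT MEF 1 (-1.03) or WT MEF 2 (-0.75), and the kinase call without WT MEF 3 (0.30), with edgeR without WT MEF 3 (0.32) and with the replicate block (0.30). The kinase median was 0.71 without G2A liver 3. Without WT MEF 3 the medians of autophagy, cell cycle and p53 genes were 0.11, -0.19 and 0.20 and the calls stood; without WT MEF 2 those of autophagy and cell cycle were 0.43 and -0.57. The autophagy median was 0.44 without G2A MEF 1, and that of the integrated stress response 0.29 without G2A MEF 2. Other settings also ended calls: for Hox genes a pseudocount of 0.1 (-3.83), no filter (-1.58), quantile normalization (-3.55), edgeR (-0.73) and DESeq2 (-0.71), and for progenitors a stricter filter (-0.63), edgeR (-0.42) and DESeq2 (-0.40). Library weights ended that of p53 targets (0.12). With the sex of the line in the model the Hox (0.21) and progenitor (-0.13) tests turned direction, and the calls of hypoxia genes (0.34) and assembly factors (-0.35) were lost. The other 21 lists did not pass, among them ER-associated degradation (0.15, adjusted p = 0.0543) and erythroid genes (-0.48, adjusted p = 0.0682).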

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

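The tests of a wrong label and of embryo stage for G2A liver 3, and those of swapped labels and of another line origin for WT MEF 3, were chosen only after the result was seen.

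The results gathered here are differences in the G2A effect, liver minus MEF on the log2 scale. Derl3 (4.15), Cox6a2 (4.68), Ppap2b (4.58), Angpt1 (4.08) and Epha3 (3.98) passed the test of the difference with higher values in liver. So did Mmp2 (3.88), Trib3 (3.38), Col3a1 (3.36), Unc5c (3.34), Col6a3 (2.81), Plagl1 (2.69), Perp (2.61), Fas (2.60), Tgfb2 (2.60), Flt1 (2.204), Ednrb (2.14), Fgfr2 (2.12), Atf5 (1.74), Pdgfrb (1.45), Creld2 (1.35), Vegfa (1.13), Me1 (1.09) and Hspa5 (0.92). Lower in liver than in MEFs were Snord53 (-8.11), C3ar1 (-5.48), Tubb3 (-3.20), Amacr (-1.92), Dock8 (-1.82), Nqo1 (-1.24), Psmb3 (-0.99), Psmd3 (-0.77), Cdc6 (-0.77), Nmt2 (-0.77), Nmt1 (-0.72), Tyms (-0.66), Nploc4 (-0.62) and Psmd9 (-0.58). Psmc1 was lower in every G2A liver and higher in every G2A MEF than in all WT libraries of its tissue, a difference of -0.77 that did not pass the test over all genes.

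By list, the median difference was -0.59 for proteasome subunits, -0.39 for assembly factors and activators, -0.38 for cell cycle, -0.55 for heme synthesis, -1.41 for haematopoietic progenitors and -3.69 for Hox genes. It was 0.50 for unfolded protein response chaperones, 0.46 for the integrated stress response, 0.31 for p53 targets, 0.27 for autophagy and lysosome, 0.57 for hypoxia and glycolysis, 0.46 for receptor tyrosine kinases, 1.14 for extracellular matrix and 1.45 for liver mesenchyme and mesothelium.

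The proteasome subunit mRNAs were lower in G2A liver and higher in G2A MEFs. With the trend on transcript length and GC content removed, the list medians were -0.16 in liver (from -0.21) and 0.30 in MEFs (from 0.38) and both calls stood at the preset correlation, which argues against that trend as the whole cause. Over both tissues and both other scalings the smallest median was 0.10 in size with both calls kept at the preset correlation, and without WT MEF 3 the MEF median was 0.35 (0.47 with WT MEF 3 as the only reference), which argues against the scaling and against WT MEF 3 as whole causes. With an estimated correlation neither call stood even before these changes (adjusted p = 0.397 in liver and 0.748 in MEFs), and fry did not call the MEF list (adjusted p = 0.246). Between livers, a lower share of dividing or red cells in G2A was not separated from a change within cells, since cell cycle and erythroid genes were lower too. An effect of the G2A genotype that differs by tissue stays open, and so does a difference between fibroblast lines, since the labels do not say how many lines each genotype had.

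G2A liver 3 stood apart from the other G2A livers in red cell genes, receptor kinases and epithelial markers but had a chaperone level like theirs. Its chaperone mean lay 0.37 above the highest WT liver, against a WT range of 0.025, which argues against a WT liver under a G2A label. WT liver 2 had the higher globin ratio and a chaperone level 0.38 lower, which argues against the share of primitive red cells or embryo stage as what sets that level. More secretory or stromal cells cannot be told apart from a change within cells: the larger excess of the mesenchyme and hepatoblast markers over the highest WT liver was 0.175, below the bound set for excluding it, but by less than the WT range. Genotype stays among the open explanations for the chaperones, and no test covered why G2A liver 3 differed in red cell genes.

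WT MEF 3 stood apart from WT MEFs 1 and 2. Of the 959 genes with a known position that differed at least 4-fold from both, 5.42% lay on chromosome X or Y (3.42% of all genes with one), which argues against sex alone, and 0 G2A libraries correlated best with WT MEF 1 or 2, which argues against a swap with G2A MEF 1 or 2. A swap with the unanalysed G2A MEF sample cannot be told apart from another line, and the partner was not examined. WT MEF 3 had a mean r of 0.956 with the G2A MEFs and 0.886 with WT MEFs 1 and 2. Its proteasome mean (-0.09) lay with WT MEFs 1 and 2 and its Hox mean (1.82) with the G2A MEFs. Hox genes were over-represented among them (20 of 30, against 7.81% of other genes; odds ratio 23.6, 95% interval 10.5 to 56.6, Fisher exact p = 1.18e-15). This is consistent with fibroblasts from another part of the embryo, a hypothesis found and tested on the same data. A single wrong label or an outside sample stays open. The labels give no group that sets WT MEF 3 apart, so beyond sex and origin no biological explanation was tested.

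For the gene counts in liver, 3 of the 10 splits of the 6 livers called as many genes as the real one (3, with 9 the highest of the others), and 3 of 10 called as many lists (19, with 19 the highest of the others). For MEFs the real split called 0 genes, so 10 of 10 called at least as many, which decides nothing. It called 10 lists, the others 5 to 15. The highest other, 1614 genes, sets WT MEFs 1 and 2 apart, a structure of the samples. In MEFs only proteasome (subunits 2.94e-15, next 1.70e-14), assembly, matrix and mesenchyme lists had their smallest camera p in the real split. With 10 splits the smallest share is 0.1, above 0.05.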

How the results depend on the processing

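The alternatives with library weights, without small RNA genes, with the sex of the MEF line, with edgeR or DESeq2, with a length and GC trend removed and without Derl3 in its list were tests chosen only after the result was seen. Gene counts are of genes past the threshold, list values are median log2 fold changes, and a list turned direction where camera's direction changed, which the median need not follow.

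The list calls depended most on the form of the list test. Camera with an estimated correlation called 0 lists higher and 0 lower in liver and 0 and 0 in MEFs, where the preset called 13, 6, 4 and 6; fry called 6, 2, 0 and 0. The estimated setting changes both the correlation and the degrees of freedom. Their shares in the loss were not separated, and p rose even where the estimate was close to the preset (MEF assembly factors, estimate 0.013, unadjusted p from 0.0027 to 0.061). Proteasome subunits stayed past the camera threshold and in direction in both tissues under each of the other alternatives run on the lists. The third G2A MEF was not used, so leaving out a G2A MEF left 1 library in that group, assumed to vary like the others. Whether read depth limited the MEF comparisons was not tested, and liver depth is unknown. Planned count tests for liver were not run, as liver values are FPKM.

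Leaving out 1 library at a time, the liver counts ranged from 1 to 1604 higher and 1 to 1548 lower (highest without G2A liver 3), and the MEF counts from 0 to 1550 higher and 0 to 1525 lower (highest without WT MEF 3). The count of genes whose effect differed between tissues ranged from 2 to 3260, their correlation from -0.10 to 0.021, and the MEF lists called lower from 3 to 9. In liver, lists that turned direction in at least 1 such fit ranged over 0.012 to 0.18 (immunoproteasome), -0.14 to 0.095 (hepatoblasts), -0.11 to 0.16 (macrophages), -0.25 to 0.10 (smooth muscle), -0.21 to -0.051 (heat shock), -0.26 to 0.11 (interferon), -0.069 to 0.0097 (cholesterol synthesis), -0.56 to 0.80 (skeletal muscle), -0.21 to -0.061 (NRF2), -0.033 to 0.089 (haematopoietic progenitors) and 0.011 to 0.20 (megakaryocytes). In MEFs they ranged over -0.86 to 0.065 (cholesterol synthesis), -0.22 to 0.27 (skeletal muscle), -0.76 to -0.50 (neural), -0.085 to 0.22 (hypoxia and glycolysis), 0.093 to 0.40 (megakaryocytes), -2.32 to 0.94 (adipocytes), -1.35 to 0.54 (immunoproteasome), -2.52 to 0.81 (interferon), -0.080 to 0.28 (cell cycle) and -1.82 to 1.37 (hepatoblasts). The log2 fold change of Itgb3 in MEF ranged from -0.083 to 0.60. Fewer samples enter each of these fits; the cause was not tested further.

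With a pseudocount of 0.1, MEF hepatoblasts turned direction (-0.77). Without a filter, so did liver interferon (-0.0089) and macrophages (-0.0025) and MEF hepatoblasts (-0.36), macrophages (-0.32) and megakaryocytes (0.10), and 29 genes differed between tissues; more genes are tested there. With a stricter filter, so did liver cholesterol synthesis (-0.034), inflammatory factors (-0.23), Hox (-0.15), smooth muscle (0.011) and skeletal muscle (0.35) and MEF neural genes (-0.71); fewer members are tested there. With median-ratio scaling, liver heat shock (-0.13) and macrophages (-0.013) turned. With quantile normalization, liver heat shock (-0.021), NRF2 (-0.067), cholesterol synthesis (0.025) and haematopoietic progenitors (-0.035) and MEF hepatoblasts (-0.72) and megakaryocytes (0.018) turned. Without a variance trend, liver heat shock (-0.12) and macrophages (-0.0025) and MEF hepatoblasts (-0.36) and skeletal muscle (0.043) turned, and 19 genes differed between tissues. The cause was not tested.

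With embryo sex in the model, liver had 4 genes higher, 152 genes differed between tissues, and liver interferon (-0.11), haematopoietic progenitors (0.0067) and macrophages (-0.046) turned. Without small RNA genes liver had 1 gene higher and 0 lower, by construction, as Mir142 and Snord53 are small RNA genes, and macrophages (-0.0025) turned. With library weights the counts were 3376 higher and 2681 lower in liver and 3149 and 2975 in MEFs, 3 MEF lists were lower and 6151 genes differed. Turned with weights were liver immunoproteasome (-0.049), inflammatory factors (-0.093), hepatoblasts (-0.20, past the threshold), haematopoietic progenitors (0.031), macrophages (-0.061), megakaryocytes (0.015), smooth muscle (0.32) and skeletal muscle (1.07), the log2 fold change of Cnn1 in liver (0.32), and MEF immunoproteasome (0.093), interferon (0.20), cell cycle (-0.075), inflammatory factors (0.054), hepatoblasts (-1.03) and megakaryocytes (0.11). The cause was not tested.

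With the sex of the line in the model, MEFs had 212 genes higher and 245 lower, 2396 genes differed between tissues and the correlation was -0.18. Turned there were MEF ER-associated degradation (-0.055), unfolded protein response (0.086), cholesterol synthesis (0.65, past the threshold), hypoxia and glycolysis (0.32, past the threshold), haematopoietic progenitors (0.045), macrophages (-0.42), skeletal muscle (0.31), adipocytes (1.78) and embryo sex (1.84), the log2 fold changes of Hsd17b7 (0.32), Cd14 (-0.23), Gp1bb (0.25) and Acta1 (0.081) in MEF, and the differences between tissues of Hox (0.21) and haematopoietic progenitors (-0.13). In that fit WT MEF 3 alone sets the WT level among libraries without the Y-linked level of WT MEFs 1 and 2. DESeq2 gave 374 higher and 627 lower in MEFs and 1429 genes that differed between tissues. Without WT MEF 3, edgeR gave 1556 and 1666, 3235 genes that differed and a correlation of 0.020. In that fit genotype cannot be told apart from sex and Hox pattern. The cause was not tested.

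With the length and GC trend removed, liver heat shock (-0.15), interferon (-0.14) and skeletal muscle (0.30) and MEF hepatoblasts (-0.49) and neural genes (0.30) turned; the neural list lost a member without a known length there.

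The correlation of deviations from group means was 0.18, -0.10 and 0.10 for the same sample numbers in liver. With 3 livers per group it cannot tell whether the number marks the littermate pairs, which the labels leave open. MEF values (0.13 and -0.03) decide nothing, as 2 G2A deviations mirror each other (r = -1). With the number as a replicate block, liver had 1 gene higher (Derl3 not among the calls), MEFs had 1891 higher and 1816 lower and 3 lists lower, 3690 genes differed between tissues and the correlation was 0.021. Liver hepatoblasts (-0.014) and macrophages (-0.0025) and MEF immunoproteasome (0.54), interferon (0.81), cell cycle (-0.080), hepatoblasts (-1.16), megakaryocytes (0.38) and cartilage and bone (0.075) turned. In the MEF block WT MEF 3 has no partner and adds nothing, so that fit is by construction close to the one without it. There too genotype cannot be told apart from sex and Hox pattern.

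Of the other comparisons between a result and its alternatives, 544 liver and 456 MEF list results, 1122 liver and 1044 MEF named-gene results and 341 list differences kept direction and side of the threshold. Lists lost the call with the direction kept in 26 liver and 26 MEF cases and gained it in 23 and 29. Named genes lost it in 3 liver cases and gained it in 127 liver and 349 MEF cases. The named differences between tissues kept the call in 173 cases and lost it in 81.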

Other observations

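The identity genes of the MEF libraries were read outside the comparisons. Hoxd13, a gene of the distal limb, was at 13210 and 12675 normalized reads in WT MEFs 1 and 2, 0 in WT MEF 3, and 105 and 6.86 in G2A MEFs 1 and 2. Hoxc6, Hoxc9 and Hoxc10, genes of the trunk, were listed at 0 in WT MEFs 1 and 2 and were at 1726, 1442 and 748 in WT MEF 3, with 1448, 1277 and 1414 in G2A MEF 1. Xist, the RNA of the inactive X chromosome, was at 2.06 and 0 in WT MEFs 1 and 2, 38335 in WT MEF 3, and 9705 and 13311 in G2A MEFs 1 and 2.

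The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 23.7, 27.6, 7.89 and 11.8 normalized reads in G2A MEF 1, which is 0.841% to 2.02% of the mean of WT MEFs 1 and 2, and were listed at 0 in WT MEF 3 and G2A MEF 2.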
